A study of Mus musculus with 20 samples.

How the data were processed

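CD45+ cells were sorted from the eyes of C57BL/6 mice aged 8 weeks into 384-well plates, and single-cell libraries of 192 wells each were made by the mCEL-Seq2 protocol, which counts transcripts by molecular identifiers, per the labels' protocols. The 20 libraries fall into 5 groups of 4: unlesioned retina (retina control), retina 3 days and 7 days after laser lesioning, cornea and ciliary body. The laser libraries are labelled CNV, the usual abbreviation of choroidal neovascularization. The series design speaks of about 6 mice in 3 independent experiments, and the labels do not say which mouse or experiment a library came from.

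Per the submitters' processing notes, reads were aligned with BWA 0.6.2-r126. The genome build, annotation and counting rules are not given in the sources used here, so genes are named by the symbols in the deposited tables and no coordinates are given. Genes with near-identical copies, among them the MHC class I genes, the Klr and Ms4a families and the neighbours Ccl2 and Ccl12, are uncertain because the treatment of shared reads is not given. The values in the deposited library tables and in the unnormalized tables are estimated counts of transcripts per gene and well, which the authors made from counts of molecular identifiers without normalization. The authors' normalized tables hold fractions: each well's unnormalized values divided by the well's total, with a largest difference of 1.1e-16, and they were not used further. The deposited annotation tables hold other values, a cell type and a cluster for each of the wells the authors kept. The retina table adds a second cell type by signature, which left many wells unassigned and named 48.8% of the day 3 dendritic cells as such. It served only as an alternative. The retina table names 511 wells as microglia, DCs (dendritic cells) or a joint class of monocytes, lymphocytes and granulocytes. The eye table names 429 wells as microglia, macrophages or that joint class. Wells were matched to libraries by exact equality of their values, after the numbering of libraries in the annotation was found to differ from that in the library names. Altogether 829 wells carry an annotation and 111 of them are in both tables.

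A well passed the filter with at least 1000 transcripts and at most 25 percent mitochondrial transcripts. Of 3840 wells, 1522 passed. The filter on wells applied to the shares of cell classes, the comparison of all retinal cells and the clustering, whereas annotated cells entered the other comparisons whether or not they passed, and 57 of them did not. No doublet caller was run, because each well received 1 sorted cell by design. Shares of cell classes are percentages of the passing wells of each library. They were compared by two-sided exact permutation tests over libraries (4 against 4, 70 arrangements), in which the smallest possible p is 0.0286 and libraries are taken as independent, with Benjamini-Hochberg adjustment over 19 tests. The classes were chosen after the annotation was read and before any p was computed. Because every call sits at the smallest possible p, the adjusted value depends on the number of tests. Intervals on counts of wells are 95 percent Wilson intervals, and a count of 0 is given with the share that 3 wells would make. Both cover counting error alone.

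For expression, the estimated counts were summed per gene over the cells of a library pair, the 2 libraries of a group that share a prefix in their names, and rounded, which gives 2 sums per group. The labels do not say that pairs are separate animals, so the p-values may measure technical spread. Sums were compared with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood test) in R 4.3.3, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Microglia and all retinal cells were each fitted over the 3 retina groups, and cells of the eye table over the 3 unlesioned compartments. Levels are counts scaled to a total of 1e6 per sum (CPM), as mean ± SD of 2 pairs. Changes are log2 ratios with a standard error (SE) equal to the size of the unshrunk log2 ratio divided by the square root of the quasi-likelihood F. Where a group held 0 transcripts, the fold is a lower bound computed with 3 transcripts over the group. Where it held 1 to 3, the ratio of summed transcripts is given with its 95 percent counting interval. Intervals and bounds cover counting error only.

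The named genes follow a rule fixed before the data were examined, as did the tests, the groups compared and the gene lists. It takes the 10 largest rises and 10 largest falls among called genes of at least 50 CPM whose pairs did not overlap, up to 4 members of each gene list with the smallest adjusted p, and a set of standard microglia, macrophage and activation genes whatever their result. The results of some of these genes are not reported here. The 27 gene lists hold pathways and cell types, 14 of them cell type markers, and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with the correlation estimated, and with fry. Camera sets a list against the other genes, and fry asks if its genes move one way on balance. No list passed in any comparison with the correlation estimated. No gene stands in more than 1 list, but a list gene can be made by other cell types too, as Fn1 of the monocyte list is.

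Wells that passed were also clustered (scanpy 1.11.5, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2) and each cluster named by its marker list. The clusters served to describe wells outside the annotation and as an alternative choice of cells. The comparison of compartments uses all cells of the eye table, as planned. It was first run on cells annotated there as macrophages or microglia alone and then returned to the plan, after both counts of genes had been seen, and the narrower choice stands among the alternatives.

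In data simulated from the means and depths of each comparison with 200 genes changed, the test recovered from 5.13% (cornea against retina) to 17.3% (microglia at day 7) of 2-fold changes. It recovered from 59.7% (all retinal cells at day 7) to 82.5% (microglia, day 7 against day 3) of 4-fold changes. For 8-fold changes the range was 79.4% (all retinal cells at day 3) to 93.8% (microglia at day 7). False calls made up 2.08% (cornea against retina) to 8.73% (microglia, day 7 against day 3) of calls.

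Alternatives planned in advance were single libraries as the unit, size factors and the Wald test of DESeq2 1.42.0, other filters on genes and wells, sums thinned to the smallest, other sets of cells, the shared prefix as a block, and leaving out each pair or library in turn. Added after seeing the data were leaving out mitochondrial genes, leaving out microglia wells with 1 percent or more photoreceptor transcripts, using only annotated retinal wells, using only microglia that the signature call also names so, and the narrower eye table. Computations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.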

Results

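The transcripts of single CD45+ cells were counted in 20 libraries of 192 wells, 4 libraries for each of unlesioned retina, retina 3 days after laser, retina 7 days after laser, cornea and ciliary body. CD45 marks cells of the haematopoietic lineage, which in the unlesioned retina are mostly microglia, the resident macrophages of nervous tissue. Library totals ran from 371329 to 3325825 estimated transcripts, both ends lying in the laser day 3 and cornea groups respectively. Of 768 wells per group, 193 passed the filter in control retina, 300 at day 3, 312 at day 7, 455 in cornea and 262 in ciliary body. Mitochondrial genes held 26.6 to 38.8% of a library's transcripts in control retina, 12.6 to 18.3% at day 3, 17.9 to 19.9% at day 7, 6.53 to 8.18% in cornea and 11.3 to 12.8% in ciliary body.

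The first question was which immune cells the retina held before and after the laser lesion. Microglia made up 54.7% ± 14.2 (SD, n = 4 libraries) of passing wells in control retina, 22.9% ± 7.15 at day 3 and 31.4% ± 4.68 at day 7. Dendritic cells, which present antigen to T cells, rose from 0% to 24% ± 7.29 at day 3 and stood at 7.62% ± 3.19 at day 7. The authors' signature call also named 48.8% of the annotated dendritic cells so at day 3 and 69.2% at day 7. Monocytes, lymphocytes and granulocytes, the authors' joint class, rose from 0% to 15% ± 5.12 at day 3 and 12.2% ± 4.55 at day 7. Among the annotated wells of control retina, 120 of 122 were microglia (98.4%, Wilson interval 94.2 to 99.6%) and 0 were dendritic cells, which allows up to 2.46%. The other 2 were of the joint class and did not pass the filter. At day 3 the annotated wells held 81 microglia, 82 dendritic cells and 46 cells of the joint class among 209. At day 7 they held 26 dendritic cells and 41 of the joint class among 180, and microglia made up 62.8% (Wilson interval 55.5 to 69.5%). By library pair, annotated microglia numbered 32 and 88 in control, 30 and 51 at day 3 and 63 and 50 at day 7. The shares of a library make up a whole, so a rise in other classes by itself lowers that of microglia. The differences in share are therefore not separate results.

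Each of the 6 differences in share from control set all 4 libraries of a group apart from all 4 of the other. This gives the smallest p the exact permutation test allows (p = 0.0286, adjusted p = 0.0452 over 19 tests). That p takes the 4 libraries of a group as independent, which the labels do not say, and 2 of them share each prefix. In control the microglia percentages went with the prefix, at 41.46 and 43.33 in P1 and 65.91 and 67.95 in P2. Those of day 3 (30.36 and 16.92 against 16.67 and 27.73) and day 7 (31.94 and 35.23 against 33.8 and 24.69) overlapped between prefixes. With 2 pairs against 2 the smallest exact p is 0.333, so no share could pass. From day 3 to day 7 the percentage of dendritic cells fell (exact permutation p = 0.0286, adjusted p = 0.0452). That of microglia did not pass (exact permutation p = 0.114, adjusted p = 0.155) and neither did that of the joint class (exact permutation p = 0.429, adjusted p = 0.452). Wells without annotation made up 45.3% ± 14.2 in control, 38.1% ± 8.76 at day 3 and 48.8% ± 8.86 at day 7. Without the mitochondrial filter on wells all 7 calls missed the threshold. The libraries still stood fully apart for dendritic cells and the joint class (adjusted p = 0.0603), with differences from control of 19.4 and 11.4 points at day 3 and 5.38 and 8.04 at day 7. Those of microglia shrank from -31.7 to -17 points at day 3 and from -23.2 to -13.5 at day 7. Each of the 6 against control also missed the threshold when any 1 control library was left out, although the remaining libraries stood fully apart. The lower share of microglia at day 7 missed it whichever of the 8 libraries was left out, and at a minimum of 500 or 2000 transcripts per well.

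**Figure D1:**
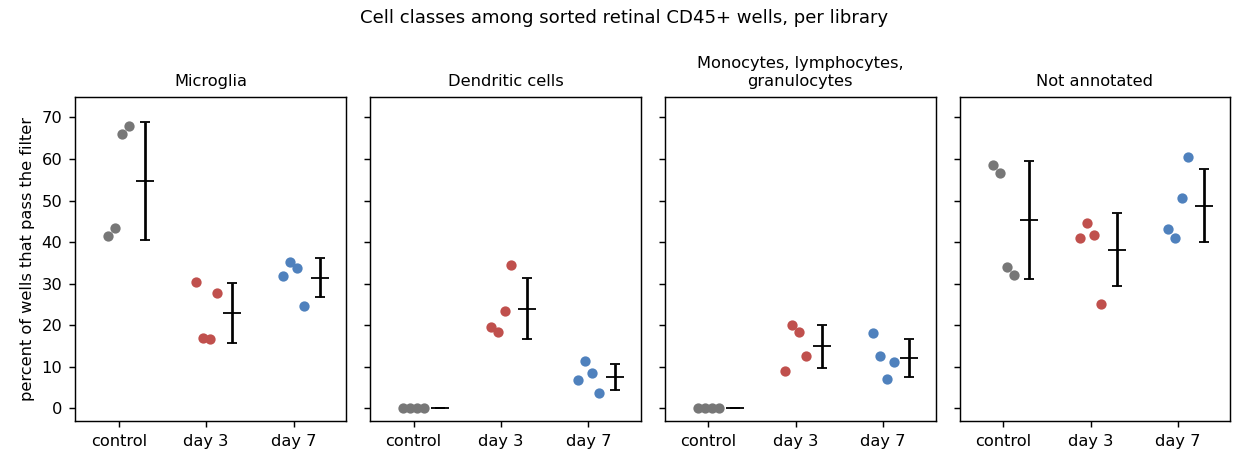
Percent of wells that pass the filter (vertical axis) by annotated class in the 3 retina groups (horizontal axis), with points for the 4 libraries of each group and bars for the mean ± SD. All 4 control libraries lie at 0 for dendritic cells and for the joint class of monocytes, lymphocytes and granulocytes, and microglia lie between 41.5 and 67.9% in control against 16.7 to 30.4% at day 3.

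How microglia themselves changed was asked by comparing annotated microglia between times. The authors' second call, by signature, also named microglia for 98.3% of them in control, 74.1% at day 3 and 87.6% at day 7. Whether the class was more mixed after laser or only expressed less of the signature was not tested. At day 3 after laser, genes that mark resting microglia were lower. P2ry12, the purine receptor that guides microglial processes, fell from 1977 ± 154 to 529 ± 58.4 CPM (SD, n = 2 pairs; log2 -1.90 ± 0.22 (SE), edgeR adjusted p = 4.02e-05). Spp1, which encodes the secreted protein osteopontin, was at 0 in control and at 249 ± 72.6 CPM at day 3, at least 38.8-fold higher (edgeR adjusted p = 2.33e-05). Top2a, a topoisomerase needed for DNA replication and mitosis, rose from 8.48 ± 12 to 245 ± 46.5 CPM (log2 4.32 ± 0.60 (SE), edgeR adjusted p = 0.000114).

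Among microglia markers 8 of 15 measured genes fell and 1 rose (adjusted over the list alone 10 and 1), with Gpr34 (log2 -1.99 ± 0.22), P2ry13 (-1.73 ± 0.23), Sall1 (-1.46 ± 0.27) and Tmem119 (-1.22 ± 0.24) among those that fell. The list as a whole was lower than other genes (camera adjusted p = 0.00165 and adjusted p = 0.343 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell by 0.97 on the log2 scale with an SE of 0.21.

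Of 18 measured genes of disease-associated microglia, a state described around lesions of the nervous system, 13 rose and 0 fell (13 adjusted over the list alone, camera adjusted p = 6.29e-07 and adjusted p = 0.169 with an estimated correlation). Cd52 (log2 1.89 ± 0.24), Cd63 (1.58 ± 0.25) and the protease gene Ctsb (1.15 ± 0.21) were among them, whereas Apoe, a lipid carrier, varied between pairs (1.34 ± 0.90, edgeR adjusted p = 0.377). Cell cycle genes rose in 16 of 19 cases (19 adjusted over the list alone, camera adjusted p = 3.61e-13 and adjusted p = 0.247 with an estimated correlation). Stmn1, a regulator of microtubules in dividing cells, rose by log2 2.78 ± 0.41, and Cdk1, the kinase that starts mitosis, was at 0 in control and at least 19.4-fold higher at day 3. The proliferation marker Mki67 stood at 280 ± 205 against 29.1 ± 0.762 CPM, which did not pass (log2 3.15 ± 0.91, edgeR adjusted p = 0.0538). Fn1, the matrix protein fibronectin, showed a ratio of 220 (counting interval 39.1 to 8730) over 1 control transcript, and Ch25h, which makes 25-hydroxycholesterol, a ratio of 74.3 (13 to 2970), also over 1.

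Interferon response genes rose in 6 of 15 cases (9 adjusted over the list alone, camera adjusted p = 6.19e-05 and adjusted p = 0.247 with an estimated correlation). Isg15 was at a ratio of 15.6 (5.02 to 78.1) over 3 control transcripts. Glycolysis genes rose in 6 of 11 cases (6 adjusted over the list alone, camera adjusted p = 0.00245 and adjusted p = 0.247 with an estimated correlation), including Gapdh (log2 2.23 ± 0.27) and Pkm (1.20 ± 0.23). Genes of oxidative phosphorylation rose in 5 of 22 (5 adjusted over the list alone, camera adjusted p = 0.00011 and adjusted p = 0.169 with an estimated correlation), among them Atp5b (log2 1.59 ± 0.27). The monocyte list had 3 measured members and 1 rose, Fn1 (camera adjusted p = 0.0219 and adjusted p = 0.247 with an estimated correlation). Immediate early genes, which respond to stimulation and tissue handling within minutes, fell in 8 of 14 cases and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00245 and adjusted p = 0.343 with an estimated correlation). Fos was at log2 -2.62 ± 0.41 and Jun at -1.88 ± 0.32. Vim, an intermediate filament gene, rose by log2 2.83 ± 0.45. The other 9 lists with at least 3 measured genes did not pass, and for MHC class I presentation the median (-0.10) and mean (0.07) log2 change differed in sign.

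Photoreceptor markers, genes that microglia are not known to express, were lower at day 3 in 4 of 16 cases (4 adjusted over the list alone, camera adjusted p = 0.00245 and adjusted p = 0.476 with an estimated correlation). Gnat1, a transducin gene of photoreceptors, stood at 335 ± 170 against 821 CPM (log2 -1.26 ± 0.28, edgeR adjusted p = 0.00424). Of 3704 genes tested, 825 differed, 394 higher and 431 lower at day 3. Without control pair P2 the count was 463, without day 3 pair P2 it was 434, and with the DESeq2 Wald test it was 307. With all annotated retinal cells in place of microglia it was 1755, and Gnat1 missed the threshold without day 3 pair P1. The median mitochondrial percentage of microglia was 6.91 and 9.57 in the control pairs and 13.3 and 12.7 at day 3. With mitochondrial genes left out 817 genes passed, but the condition of the cells was not tested apart from time. In the microglia that the signature call also named so, 594 genes passed. There P2ry12, Gpr34, Tmem119, Spp1, Top2a and Fn1 kept their calls, and Mki67 passed. The genes behind that call are not given, and choosing wells by it may itself lessen falls in microglia markers.

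At day 7 fewer genes separated microglia from control, and the microglial receptors were again lower. P2ry12 stood at 837 ± 67.2 CPM, lower than control by log2 -1.24 ± 0.21 (SE, n = 2 pairs, edgeR adjusted p = 0.0157). Axl, a receptor for the uptake of dying cells, rose from 78.4 ± 57.0 to 325 ± 11.2 CPM (log2 1.86 ± 0.37, edgeR adjusted p = 0.0245). Itgax, which encodes the integrin CD11c, showed a ratio of 37.2 (counting interval 6.31 to 1510) over 1 control transcript, and Fn1 a ratio of 29.8 (4.98 to 1210), also over 1.

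Of the disease-associated microglia genes 6 of 18 rose (8 adjusted over the list alone, camera adjusted p = 4.37e-07 and adjusted p = 0.174 with an estimated correlation), including Cd63 (log2 1.30 ± 0.26), Cd52 (1.29 ± 0.24) and Ctsb (1.10 ± 0.21). Spp1 was at least 5.90-fold higher than in control. Apoe was at 6424 ± 673 against 568 ± 264 CPM, which did not pass (log2 3.45 ± 0.94, edgeR adjusted p = 0.272). Ftl1, an iron storage gene (1.39 ± 0.24), and the secreted glycoprotein gene Lgals3bp (1.63 ± 0.32) also rose. Microglia markers fell in 4 of 15 cases (9 adjusted over the list alone, camera adjusted p = 3.26e-05 and adjusted p = 0.212 with an estimated correlation): P2ry12, P2ry13 (-1.18 ± 0.22), Tmem119 (-1.18 ± 0.24) and Gpr34 (-0.95 ± 0.21). Interferon response genes rose in 1 of 15 cases, Cxcl10, and in 10 adjusted over the list alone (camera adjusted p = 2.59e-09 and adjusted p = 0.196 with an estimated correlation). H2-Aa, an MHC class II chain, rose by log2 1.24 ± 0.28 and H2-D1 of MHC class I by 0.99 ± 0.23.

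Immediate early genes fell in 2 of 14 cases, Fos (log2 -1.88 ± 0.39) and Jun (-1.62 ± 0.32), and in 8 adjusted over the list alone (camera adjusted p = 4.78e-05 and adjusted p = 0.201 with an estimated correlation). Dusp6, a phosphatase that limits ERK signalling (-1.84 ± 0.35), and Nkain3 (-1.75 ± 0.29) also fell. No photoreceptor marker passed, and 4 of 16 rose adjusted over the list alone (camera adjusted p = 3.27e-06 and adjusted p = 0.214 with an estimated correlation). Camera also called the lists of monocyte markers, Müller glia and astrocyte markers, MHC class II presentation, NF-kB targets, oxidative phosphorylation and lysosome genes as higher, with adjusted p from 0.000298 to 0.0309 and, with an estimated correlation, adjusted p from 0.196 to 0.34. The corneal list had a median (-0.25) and mean (-0.41) below 0 and a test direction above.

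At day 7, 37 of 3704 genes passed, 24 higher and 13 lower. With sums thinned to the smallest, 0 genes passed in edgeR, whereas 506 had an unadjusted p under 0.05 in the full sums and DESeq2 called 19. The count was 89 without control pair P1, 142 with single libraries and 775 with all annotated retinal cells. Without control pair P2 it was 76, with 29 higher and 47 lower. With the signature call as well it was 19, where Apoe passed and Tmem119, Gpr34, Spp1, H2-Aa, H2-D1, Cxcl10 and Nkain3 missed the threshold. P2ry12 and Tmem119 missed the threshold without day 7 pair P2, and Lgals3bp, Cd52, P2ry13 and Jun without day 7 pair P1. Itgax, Spp1 and Fos missed it without control pair P2, and Cd63, Ctsb, Gpr34, H2-Aa, H2-D1 and Cxcl10 without at least 1 pair.

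**Figure D2:**
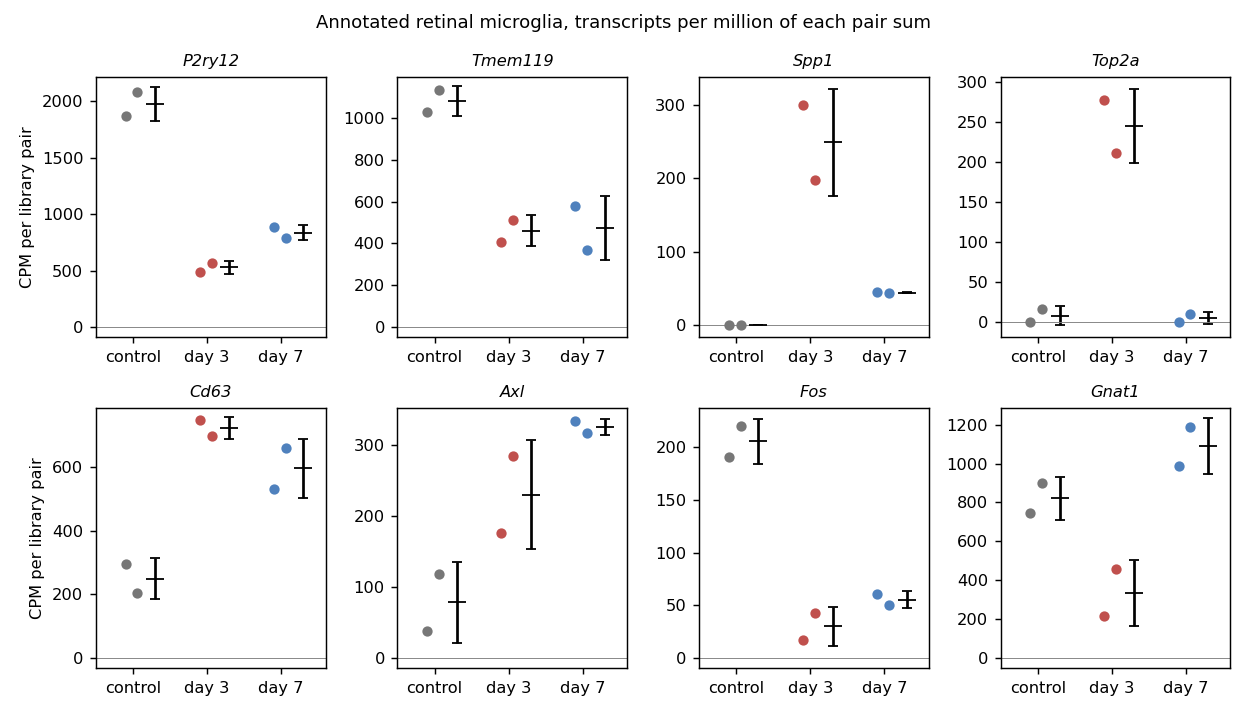
CPM (vertical axes) of 8 genes in annotated retinal microglia of control, day 3 and day 7 retina (horizontal axes), with points for library pairs and bars for the mean ± SD of 2 pairs. P2ry12 lies at 1977 CPM in control against 529 at day 3 and 837 at day 7, while Top2a lies at 245 CPM at day 3 against 8.48 in control and 5.56 at day 7.

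Day 7 set directly against day 3 asked which changes differed between the times. Genes of cell division were lower at day 7. Top2a had 2 transcripts at day 7 against 123 at day 3, a ratio of 0.0159 (counting interval 0.0019 to 0.0586). The chromatin gene Hmgb2 fell from 406 ± 124 to 70.1 ± 18.8 CPM (SD, n = 2 pairs; log2 -2.53 ± 0.36, edgeR adjusted p = 0.000551). Spp1 fell by 2.43 on the log2 scale with an SE of 0.38, Fn1 by 2.57 with 0.31, and Lpl, the lipoprotein lipase gene, by 1.70 with 0.35. H2-D1 was higher at day 7 (log2 1.21 ± 0.23, edgeR adjusted p = 0.00361), as was the phagocytic receptor gene Trem2 (0.85 ± 0.23, edgeR adjusted p = 0.0247).

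The cell cycle list was lower in 13 of 19 cases (19 adjusted over the list alone, camera adjusted p = 1.28e-16 and adjusted p = 0.339 with an estimated correlation). Ube2c was at log2 -4.40 ± 0.63 and Stmn1 at -2.67 ± 0.38. Glycolysis genes were lower in 4 of 11 cases (4 adjusted over the list alone, camera adjusted p = 0.0186 and adjusted p = 0.339 with an estimated correlation), including Gapdh (-1.43 ± 0.25). Disease-associated microglia genes were lower in 6 of 18 cases (7 adjusted over the list alone) without a call for the list (camera adjusted p = 0.0601). Among microglia markers 1 was higher, Gpr34 (1.04 ± 0.22), and 1 lower, Fcrls (-0.97 ± 0.23), and P2ry12 did not pass (0.66 ± 0.22, edgeR adjusted p = 0.0634). Csf3r, a receptor for granulocyte growth factor, was higher by log2 1.39 ± 0.28. For the interferon, matrix remodelling, lysosome and lipid lists the median and mean log2 change differed in sign, with camera adjusted p = 0.984 for each.

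Photoreceptor markers were higher at day 7 in 11 of 16 cases (15 adjusted over the list alone, camera adjusted p = 1.47e-11 and adjusted p = 0.339 with an estimated correlation). Gnat1 was at 1088 ± 144 against 335 ± 170 CPM (log2 1.65 ± 0.28). Without the microglia wells holding 1 percent or more photoreceptor transcripts, Gnat1 was still higher and past the threshold. Of 3704 genes 336 passed, 175 of them higher at day 7 and the others lower. The count was 180 without day 3 pair P1, 142 without day 3 pair P2, 88 with the DESeq2 Wald test and 218 with all annotated retinal cells, where H2-Aa turned from 1.10 to -0.64. With the signature call as well it was 179, where Apoe and Mki67 passed and Spp1, Trem2 and H2-Aa missed the threshold. Gpr34 and Csf3r missed the threshold without day 3 pair P1, and Trem2 and Fcrls without any 1 pair.

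All passing retinal wells were summed to describe the whole sorted population, in which changes in the mix of cells and within cells are joined. At day 3 genes of antigen presentation, monocytes and dendritic cells were higher, and those of microglia and photoreceptors lower. Cd74, the invariant chain of MHC class II, rose from 37.3 ± 13.4 to 6189 ± 1130 CPM (SD, n = 2 pairs; log2 7.36 ± 0.55, edgeR adjusted p = 0.000113). Itgax showed a ratio of 127 (counting interval 43.3 to 618) and Ccr2, the receptor that draws monocytes from blood, a ratio of 140 (38.5 to 1160), over 3 and 2 control transcripts. P2ry12 fell from 692 ± 407 to 157 ± 17.7 CPM (log2 -2.14 ± 0.43, edgeR adjusted p = 0.00666).

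Dendritic cell markers rose in 13 of 16 cases (15 adjusted over the list alone, camera adjusted p = 3.99e-10 and adjusted p = 0.364 with an estimated correlation). Kmo was at 0 in control and at least 43.3-fold higher. Monocyte markers rose in 9 of 11 (10 adjusted over the list alone, camera adjusted p = 8.69e-08 and adjusted p = 0.325 with an estimated correlation). Genes of MHC class II presentation rose in 9 of 10 (9 adjusted over the list alone, camera adjusted p = 5.82e-09 and adjusted p = 0.364 with an estimated correlation). H2-Aa was at log2 4.37 ± 0.38. Those of MHC class I rose in 8 of 10 (10 adjusted over the list alone, camera adjusted p = 3.25e-06 and adjusted p = 0.434 with an estimated correlation). Interferon response genes rose in 14 of 20 (16 adjusted over the list alone, camera adjusted p = 5.82e-09 and adjusted p = 0.464 with an estimated correlation). Cell cycle genes rose in 17 of 21 (20 adjusted over the list alone, camera adjusted p = 9.02e-13 and adjusted p = 0.325 with an estimated correlation). Il1b, the cytokine interleukin 1 beta, rose by log2 4.20 ± 0.57 and Vim by 5.45 ± 0.56.

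T cell markers rose in 2 of 10 cases (4 adjusted over the list alone, camera adjusted p = 0.0107 and adjusted p = 0.513 with an estimated correlation). NK and innate lymphoid markers rose in 2 of 8 and fell in 1 (3 and 1 adjusted over the list alone, camera adjusted p = 0.024 and adjusted p = 0.513 with an estimated correlation). Klrd1, a receptor of NK cells and some T cells, showed a ratio of 192 (34.3 to 7620) over 1 control transcript. It was also a leading gene of a dendritic cell-like cluster with 89 day 3 wells, so its rise need not come from NK or T cells. Disease-associated microglia genes rose in 10 of 22 (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.94e-07 and adjusted p = 0.325 with an estimated correlation). Microglia markers fell in 6 of 15 (8 adjusted over the list alone, camera adjusted p = 0.0107 and adjusted p = 0.577 with an estimated correlation). Photoreceptor markers fell in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 1.99e-11 and adjusted p = 0.464 with an estimated correlation). Pde6g, a phosphodiesterase gene of photoreceptors, was at 378 ± 201 against 3657 ± 1340 CPM, and missed the threshold in annotated wells alone. Control library P1-1, with 5.63% photoreceptor transcripts over all its wells the highest of its group, supplied 529095 of the 668359 transcripts of control pair P1, here and at day 7. Without that pair Pde6g kept its call at day 3. Camera also called pigment epithelium and glycolysis genes as lower and NF-kB, matrix remodelling and lysosome genes as higher, with adjusted p from 0.00695 to 0.0322 and adjusted p = 0.513 for each with an estimated correlation. For tissue macrophage and neutrophil markers the median lay below 0 and the mean above.

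Of 9334 genes 2133 passed at day 3, 1184 higher and 949 lower. The count was 1199 without day 3 pair P1 and 992 without day 3 pair P2, and 1755 in annotated wells alone, among which the glycolytic gene Aldoa turned from log2 -1.37 to 0.13.

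In the same population at day 7, genes of T cells and of antigen presentation were higher than in control. Cd8a, the co-receptor of cytotoxic T cells, was at 0 in control and at 57.8 ± 6.68 CPM at day 7 (n = 2 pairs), at least 24.5-fold higher (edgeR adjusted p = 0.0046). Ccl5, a chemokine made by T cells, rose from 20.2 ± 0.88 to 461 ± 260 CPM (log2 4.50 ± 0.53, edgeR adjusted p = 0.00517). Cd74 rose from 37.3 ± 13.4 to 1844 ± 974 CPM (log2 5.62 ± 0.52, edgeR adjusted p = 0.00215). Ms4a4b, a T cell membrane gene, showed a ratio of 111 (counting interval 30.4 to 917) and the cytotoxic granule gene Nkg7 a ratio of 101 (17.9 to 4030), over 2 and 1 control transcripts.

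T cell markers rose in 4 of 10 cases (10 adjusted over the list alone, camera adjusted p = 1.5e-16 and adjusted p = 0.192 with an estimated correlation). Dendritic cell markers rose in 5 of 16 (11 adjusted over the list alone, camera adjusted p = 1.15e-14 and adjusted p = 0.192 with an estimated correlation). Monocyte markers rose in 4 of 11 (8 adjusted over the list alone, camera adjusted p = 2.59e-10 and adjusted p = 0.192 with an estimated correlation). Ly6c2 was at log2 5.10 ± 0.68. Genes of MHC class II presentation rose in 6 of 10 (8 adjusted over the list alone, camera adjusted p = 9.08e-13 and adjusted p = 0.192 with an estimated correlation). H2-Aa was at 2.99 ± 0.36. Interferon response genes rose in 6 of 20 (15 adjusted over the list alone, camera adjusted p = 2.89e-16 and adjusted p = 0.233 with an estimated correlation). Isg15 was at 4.31 ± 0.60. Apoe rose by log2 2.16 ± 0.38. Microglia and photoreceptor markers had no member past the threshold (4 and 0 fell adjusted over each list alone, camera adjusted p = 8.45e-06 and 4.27e-06, both lower and adjusted p = 0.471 for each with an estimated correlation). Camera also called cell cycle, MHC class I, NK, disease-associated microglia, NF-kB and matrix remodelling genes as higher and glycolysis genes as lower, with adjusted p from 2.59e-10 to 0.0242 and, with an estimated correlation, adjusted p from 0.192 to 0.654. The median, mean and test differed in sign for the tissue macrophage, neutrophil, corneal, pigment epithelium, complement and oxidative phosphorylation lists, none of which passed.

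Of 9334 genes 1.21% passed at day 7, all of them higher. The count was 293 without control pair P2, 42 without day 7 pair P1, 264 with single libraries and 468 without the filter on low counts. In annotated wells alone 775 passed, 469 higher and 306 lower. Without control pair P1 76 were higher and 26 lower. Apoe missed the threshold without either day 7 pair, Ly6c2 without either control pair and Nkg7 without control pair P1.

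A further question was how macrophages differ between compartments of the unlesioned eye. In the eye table all annotated wells of control retina were microglia (100%, Wilson interval 96.9 to 100%), against 0 wells in cornea, which allows up to 2.38%, and 0 of 184 in ciliary body, which allows up to 1.63%. Macrophages made up 121 of the annotated cornea wells (96%, Wilson interval 91.1 to 98.3%) and 111 of the 184 of ciliary body (60.3%, 53.1 to 67.1%). As a share of passing wells, monocytes, lymphocytes and granulocytes made up 27.3% ± 2.42 (SD, n = 4 libraries) in ciliary body, 1.60% ± 2.25 in cornea and 0% in control retina. Macrophages made up 23.9% ± 11.4 in cornea and 41.2% ± 3.63 in ciliary body, and wells without annotation 74.5% ± 10.2 in cornea, 31.6% ± 5.01 in ciliary body and 46.6% ± 11.3 in control retina.

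The joint class differed between ciliary body and both other compartments, unannotated wells between cornea and both others, and macrophages between cornea and ciliary body (exact permutation p = 0.0286, adjusted p = 0.0452 for each of the 5). These p-values too take libraries as independent, and with 2 pairs against 2 none could pass. The shares count every passing well, with or without annotation. Of the passing cornea wells without annotation, 283 of 333 fell into corneal epithelium and keratocyte-like clusters. Among annotated wells the order of macrophages was the reverse, with 96% in cornea against 60.3% in ciliary body. The joint class in cornea against retina (exact permutation p = 0.429, adjusted p = 0.452) and unannotated wells in ciliary body against retina (exact permutation p = 0.0857, adjusted p = 0.125) did not pass. Without the mitochondrial filter all 5 calls missed the threshold. The joint class of ciliary body still stood fully apart from both others, by 24.9 and 23.5 points, and unannotated wells of cornea from ciliary body, by 37.8. Unannotated wells of cornea against retina shrank from 27.9 to 12.6 points. The calls against retina also missed the threshold when any 1 control library was left out, and that for macrophages when any 1 ciliary body library was.

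Cornea cells of the eye table had less of the microglia markers and more of single genes such as Mrc1 and H2-Aa. P2ry12 stood at 55.4 ± 18.5 against 1874 ± 97.3 CPM in retina (SD, n = 2 pairs; log2 -5.07 ± 0.34, edgeR adjusted p = 3.69e-06). Mrc1, the mannose receptor of tissue macrophages, was at 0 in retina and 255 ± 48 CPM in cornea, at least 42.7-fold higher (edgeR adjusted p = 0.00129). H2-Aa stood at 10710 against 521 CPM (log2 4.38 ± 0.39) and Il1b at 2195 against 18 CPM (6.70 ± 0.43), both at an edgeR adjusted p of at most 1.05e-05.

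All 15 measured microglia markers were lower (15 adjusted over the list alone, camera adjusted p = 5.58e-13 and adjusted p = 0.31 with an estimated correlation). Tmem119 was at log2 -3.75 ± 0.30. Tissue macrophage markers were higher in 4 of 8 cases (4 adjusted over the list alone, camera adjusted p = 0.0127 and adjusted p = 0.31 with an estimated correlation). Ms4a7 was at 0 in retina and at least 28.9-fold higher. Monocyte markers were higher in 5 of 9 (5 adjusted over the list alone, camera adjusted p = 0.0142 and adjusted p = 0.347 with an estimated correlation). Ccr2 was at a ratio of 123 (counting interval 21.8 to 4910) over 1 retina transcript. Genes of MHC class II presentation were higher in 6 of 10 and lower in 1 (7 and 2 adjusted over the list alone) without a call for the list (camera adjusted p = 0.0555). Cell cycle genes were higher in 7 of 8 (8 adjusted over the list alone, camera adjusted p = 0.00536 and adjusted p = 0.347 with an estimated correlation). Interferon response genes were higher in 4 of 14 (3 adjusted over the list alone, camera adjusted p = 0.0335 and adjusted p = 0.364 with an estimated correlation). Genes of angiogenesis and matrix remodelling were higher in 8 of 14 and lower in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0134 and adjusted p = 0.31 with an estimated correlation), with Mmp13, a collagenase, at 0 in retina and at least 34.8-fold higher.

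Lysosome and phagocytosis genes were lower in 8 of 18 cases and higher in 3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0222 and adjusted p = 0.31 with an estimated correlation). They included the protease gene Ctsd (log2 -4.16 ± 0.31) and the receptors Mertk (-4.42 ± 0.38) and Trem2 (-3.44 ± 0.32). Apoe was higher (3.77 ± 0.36), as was Lgals3, which encodes galectin 3 (4.34 ± 0.42). For MHC class I presentation the median (-0.19) and mean (0.01) differed in sign, and for glycolysis the median (0.19) and mean (0.30) lay above 0 with a test direction below.

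Immediate early genes were higher in cornea in 18 of 19 cases (18 adjusted over the list alone, camera adjusted p = 9.29e-09 and adjusted p = 0.347 with an estimated correlation). Fosb was at log2 6.04 ± 0.54 and Atf3 at 6.43 ± 0.55. NF-kB targets and cytokines were higher in 15 of 18 (16 adjusted over the list alone, camera adjusted p = 1.64e-08 and adjusted p = 0.31 with an estimated correlation). The chemokine gene Cxcl2 was at 8.39 ± 0.60. Compartment and tissue preparation coincide, so for these lists a difference in handling cannot be told apart from one between the cells. Corneal epithelial markers were higher in 3 of 10 (3 adjusted over the list alone, camera adjusted p = 0.0126 and adjusted p = 0.31 with an estimated correlation). The keratin gene Krt15 was at 224 ± 92.8 against 17.6 ± 24.8 CPM. Photoreceptor markers were lower in 3 of 14 (2 adjusted over the list alone, camera adjusted p = 0.000284 and adjusted p = 0.38 with an estimated correlation). Of 4657 genes 1638 passed, 881 higher and 757 lower in cornea. The count was 869 without retina pair P2 and 1034 with sums thinned to the smallest, and Krt15 missed the threshold without any 1 pair of either group.

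Cells of the ciliary body, the ring of tissue that makes aqueous humour, differed from retinal microglia in genes of microglia, monocytes, antigen presentation and the immediate early response. P2ry12 stood at 63.0 ± 6.96 CPM (n = 2 pairs; log2 -4.89 ± 0.32 against retina, edgeR adjusted p = 3.77e-06). H2-Aa stood at 10610 ± 2990 CPM (4.36 ± 0.39, edgeR adjusted p = 1.2e-05) and Il1b at 2567 ± 303 CPM (6.93 ± 0.44, edgeR adjusted p = 3.77e-06). Ccr2 showed a ratio of 98.3 (counting interval 17.5 to 3890) over 1 retina transcript, and F13a1, a coagulation factor gene of macrophages and monocytes, was at 0 in retina and at least 7.90-fold higher.

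All 15 microglia markers were lower (15 adjusted over the list alone, camera adjusted p = 1.16e-13 and adjusted p = 0.198 with an estimated correlation). Tmem119 was at log2 -3.99 ± 0.30 and Gpr34 at -4.07 ± 0.30. Monocyte markers were higher in 9 of 9 cases (9 adjusted over the list alone, camera adjusted p = 7.55e-06 and adjusted p = 0.198 with an estimated correlation). Tissue macrophage markers were higher in 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00452 and adjusted p = 0.198 with an estimated correlation). Genes of MHC class II presentation were higher in 7 of 10 and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00165 and adjusted p = 0.198 with an estimated correlation). Dendritic cell markers were higher in 5 of 8 and lower in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00657 and adjusted p = 0.198 with an estimated correlation). Ccl22 was at 0 in retina and at least 16.3-fold higher. NK and innate lymphoid markers were higher in 2 of 6 (2 adjusted over the list alone, camera adjusted p = 0.0177 and adjusted p = 0.198 with an estimated correlation). The eye table of ciliary body holds 73 wells of the joint class.

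Immediate early genes were higher in 16 of 19 cases (18 adjusted over the list alone, camera adjusted p = 7.77e-09 and adjusted p = 0.27 with an estimated correlation). Fosb was at log2 5.19 ± 0.55. NF-kB targets were higher in 14 of 18 (14 adjusted over the list alone, camera adjusted p = 1.7e-08 and adjusted p = 0.198 with an estimated correlation). Cxcl2 was at 6.94 ± 0.59. Lysosome genes were lower in 7 of 18 and higher in 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0153 and adjusted p = 0.198 with an estimated correlation). Ctsd was at -2.77 ± 0.28, Mertk at -3.62 ± 0.31 and Trem2 at -2.88 ± 0.29. Apoe was higher by 4.38 ± 0.37 and Ifitm3, an interferon-induced antiviral gene, by 3.39 ± 0.35. Photoreceptor markers were lower in 5 of 14 (7 adjusted over the list alone, camera adjusted p = 1.83e-06 and adjusted p = 0.319 with an estimated correlation). Camera also called matrix remodelling, interferon, cell cycle and oxidative phosphorylation genes as higher, with adjusted p from 0.00299 to 0.023 and, with an estimated correlation, adjusted p from 0.198 to 0.27, and for neutrophil markers the median (-0.88) and mean (0.42) differed in sign. Of 4657 genes 1421 passed, 825 higher and 596 lower. The count was 735 without retina pair P2, 922 with thinned sums and 932 with wells of microglia-like and macrophage-like clusters, in which Anxa2 turned from higher to lower.

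**Figure D3:**
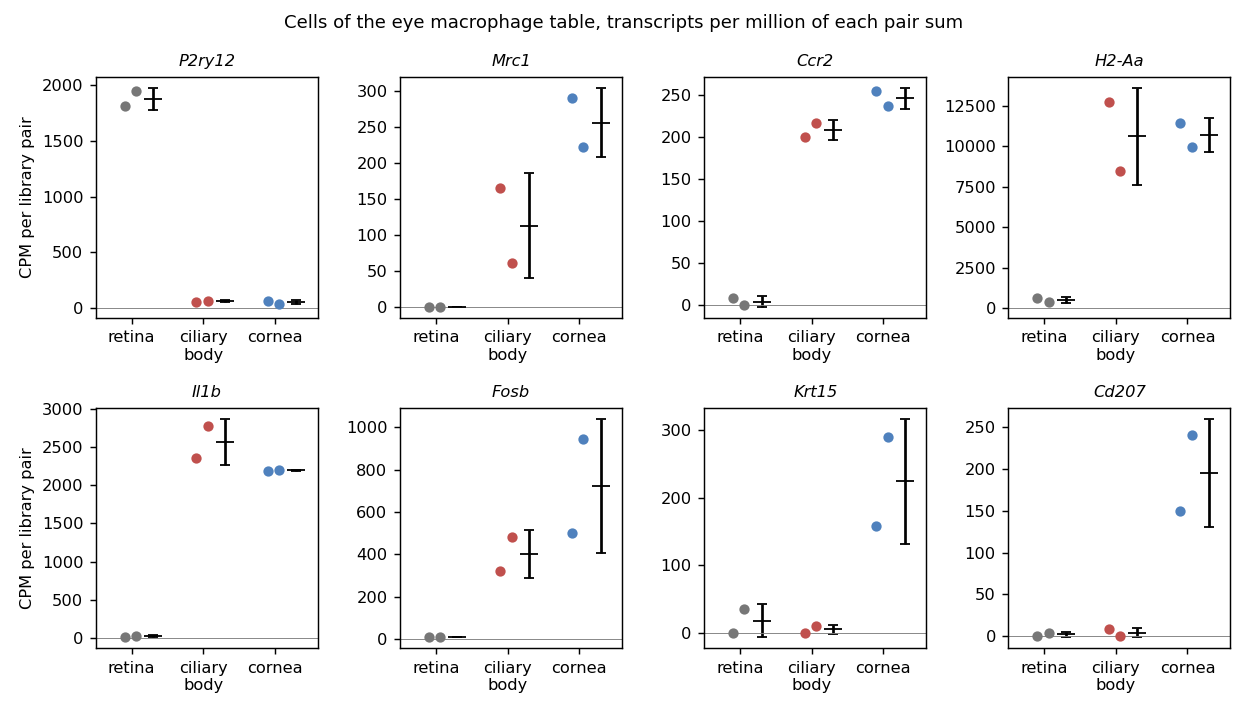
CPM (vertical axes) of 8 genes in cells of the eye table from control retina, ciliary body and cornea (horizontal axes), with points for library pairs and bars for the mean ± SD of 2 pairs. P2ry12 lies at 1874 CPM in retina against 63.0 in ciliary body and 55.4 in cornea, whereas Cd207 lies at 195 CPM in cornea against 4.14 in ciliary body.

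Cornea and ciliary body were also set against each other. These sums include the joint class of monocytes, lymphocytes and granulocytes, which made up 39.7% of annotated wells in ciliary body and 3.97% in cornea. Differences in the mix of cells therefore enter the genes and lists below. With only macrophages and microglia in the fit 158 genes passed, 124 of them shared with the sums of all cells. Cornea cells had more Cd207, which encodes langerin, a lectin of Langerhans-like cells, at 195 ± 64.8 against 4.14 ± 5.86 CPM (SD, n = 2 pairs; log2 5.68 ± 0.68, edgeR adjusted p = 0.000816). The chemokine gene Ccl2 was higher in cornea (510 ± 52.5 against 70.3 ± 24.9 CPM, log2 2.87 ± 0.31, edgeR adjusted p = 0.00041). Also higher were Scd2 (2.56 ± 0.34) and Hmgcs1 (1.70 ± 0.34) of lipid and sterol synthesis and the oxygen sensor gene Egln3 (4.11 ± 0.46). Ciliary body cells had more Tmsb10, an actin-binding protein gene (445 ± 73.7 against 88.7 ± 28.6 CPM, log2 -2.32 ± 0.31 for cornea over ciliary body, edgeR adjusted p = 0.000857). F13a1 had 2 transcripts in cornea and 74 in ciliary body, a ratio of 0.0672 (counting interval 0.00799 to 0.252).

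P2ry12 (log2 -0.18 ± 0.33), Ccr2 (0.24 ± 0.29), Mrc1 (1.21 ± 0.45), H2-Aa (0.01 ± 0.33) and Cd74 (-0.16 ± 0.38) did not pass. Monocyte markers had 0 of 9 past the threshold and 7 lower in cornea adjusted over the list alone (camera adjusted p = 4.05e-05 and adjusted p = 0.248 with an estimated correlation). Dendritic cell markers had 0 of 8 past it and 4 lower adjusted over the list alone (camera adjusted p = 0.000263 and adjusted p = 0.248 with an estimated correlation). Among genes of MHC class II presentation H2-Oa (-1.97 ± 0.48) and H2-Ob (-1.79 ± 0.44) were lower in cornea, 2 of 10 (2 adjusted over the list alone), without a call for the list (camera adjusted p = 0.149). Camera also called microglia, NK, neutrophil and MHC class I lists as lower and immediate early genes as higher in cornea, each with an adjusted p of 0.026 or 0.0265. The photoreceptor and complement lists were higher just inside the threshold, with an adjusted p that rounds to 0.05. With an estimated correlation the adjusted p of these 7 lists ran from 0.373 to 0.638. For mast cell and glycolysis lists the test direction differed from the median and mean, and for the lipid list the median (-0.13) from the mean (0.37).

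Corneal epithelial markers were higher in cornea in 3 of 10 cases (3 adjusted over the list alone, camera adjusted p = 4.05e-05 and adjusted p = 0.248 with an estimated correlation). Krt15 was at log2 5.31 ± 0.86. Other epithelial genes were among the largest differences, including Psca (5.40 ± 0.58) and Aqp5, an aquaporin (6.00 ± 0.76). Of 4657 genes 3.67% passed, 118 higher and 53 lower in cornea. The count was 283 without ciliary body pair P4, 313 without cornea pair P2 (35.5% higher in cornea), 72 without cornea pair P5, 102 with the DESeq2 Wald test and 97 with thinned sums. With single libraries it was 294, of which 38.8% were higher in cornea against 69% in the pair sums, and without the filter on low counts it was 425. Krt15 and Aqp5 missed the threshold without either cornea pair, F13a1 without ciliary body pair P3, and H2-Oa and H2-Ob without cornea pair P5 and at least 1 other pair.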

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

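The tests of the immediate early genes with only macrophages and microglia and with thinned sums were chosen after the result was seen.

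Microglia of day 7 and day 3 differed from each other in 336 of 3704 genes, a direct test of the difference between the times. Cell cycle genes such as Top2a and the lesion genes Spp1 and Fn1 were lower at day 7, and H2-D1 and photoreceptor genes such as Gnat1 were higher. Outside the authors' annotation, 283 of 333 passing cornea wells (85%) fell into clusters named by corneal epithelium and keratocyte markers, against 8 of 76 (10.5%) in control retina. At day 7, 59 of 152 such wells (38.8%) were photoreceptor-like, against 21 of 76 (27.6%) in control retina. The sort for CD45 is meant to leave out epithelial cells and photoreceptors, yet these wells passed the filter and count in the shares of passing wells. In the photoreceptor-like clusters 16 markers were higher in each, at 2.748 and 0.8135 times the median transcripts of passing wells in their library. In the corneal clusters 6, 4 and 12 were higher, at 2.001, 2.286 and 0.4715 times. A cluster's name rests on its marker list alone.

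In 4 of 25 sets of 4 libraries a library lay far from the others, by the share of the range taken up by its gap to the next library. The limit used is one that chance passes in about 1 of 20 sets of independent normal values. In ciliary body the mitochondrial percentage of library P4-1 was 12.77, and that of the others ran from 11.26 to 11.47. In control retina library P1-1 held 5.631% photoreceptor transcripts, the others 3.164 to 3.359%. At day 3 library P2-2 had 61.98% of its wells past the filter and 52.08% annotated, and its total of 1130863 transcripts was the highest of its group.

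Gnat1 and other photoreceptor genes were higher in day 7 than in day 3 microglia, with Gnat1 at 1088 CPM at day 7. The top 10% of day 7 microglia wells held 37.41% of these transcripts, under the 50% set in advance. That share includes transcripts that day 3 microglia also hold, so by itself it cannot exclude a few wells with photoreceptor material as the cause. The median well was higher too, at 0.288 and 0.528% in the day 7 pairs against 0.102 and 0.153% at day 3. A few wells alone would not give that. Free photoreceptor RNA shared by every well of a library remains a candidate explanation: microglia and the other annotated cells of a laser library held alike percentages (median ratio 1.031, from 0.9405 to 2.098 over 8 libraries, above 1 in 7). Over all wells, photoreceptor transcripts made up 0.6859 to 1.1% of a library at day 3, 1.55 to 4.773% at day 7 and 3.164 to 5.631% in control. The median control microglia well held 0.170 and 0.392% in the 2 pairs. Library content and microglia thus ran together from day 3 to day 7, and less plainly between control and day 7. Uptake of photoreceptor material by microglia after the lesion stays open and was not tested. No photoreceptor list gene stands in another list.

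Keratin genes appeared in cornea cells annotated as macrophages or joint-class cells, with Krt12 at 5843 and Krt5 at 3082 CPM. A few wells that also hold epithelial cells were excluded as the whole cause, since the top 10% of wells held 45.52% of the corneal marker transcripts, under the 50% set in advance. Free epithelial RNA in every well remains a candidate source. Krt5 or Krt12 was held by 100% of annotated cornea wells, against 40.76% in ciliary body and 36.13% in control retina. The median corneal percentage was 1.241, 0.03587 and 0.02462. Control retina was uneven: its microglia in the retina table had Krt12 at 0 CPM in pair P1 and 513 in P2, and Krt5 at 0 and 97.5. Uptake of epithelial material by cornea macrophages is a biological alternative that was not tested. Higher Krt15, Psca and Aqp5 in cornea could therefore come from either.

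Immediate early genes such as Fosb and Fos were higher in cornea and ciliary body than in retina, with list medians of 3.18 and 2.40 on the log2 scale, among which Nr4a2 lies above the median also at its bound. Monocytes, lymphocytes and granulocytes in the table were excluded as the whole cause, since the lower median was 2.36 with only macrophages and microglia. The lower median was 2.19 with thinned sums. Thinning leaves expected ratios unchanged and does not alter depth per well, so it cannot exclude the greater depth of the ciliary body cells. Cornea had the higher list median at a depth near that of retina, with pair medians of 3686 and 3793 transcripts per well against 4241 and 3435. Tissue preparation remains a candidate explanation. The joint class held 6.433 times the immediate early percentage in ciliary body (1.17 ± 0.297, n = 4 libraries) as in laser retina (0.1962 at day 3 and 0.1675 at day 7). The class need not hold the same cells in both tissues. A cluster led by the mast cell genes Tpsb2 and Cma1 and the NK gene Gzma had 38 ciliary body wells against 6 at each day. T cell-like wells numbered 1 against 8 at day 3 and 30 at day 7. The ratio therefore does not separate preparation from cell type. A biological difference between compartments stays open and untested, because compartment and preparation coincide. The same holds for the NF-kB targets and cytokines, which were also higher in cornea and ciliary body than in retina.

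The count of genes in the sums of single libraries was set against the 35 splits of the same 8 libraries. Only 3 of these keep every pair whole, too few for a share under 0.05. What follows holds only if libraries that share a prefix are independent, which the labels do not say. Over all wells, the chi-square per gene between 2 libraries was lower within a prefix in cornea (4.032 and 4.356) than between prefixes (13.47 to 15.23). So it was in ciliary body (3.754 and 2.976 against 5.91 to 9.294), which argues against the condition there. Retina was mixed, with 9.234 and 3.628 within a prefix in control (between prefixes 6.46 to 9.299). At day 3 they were 3.453 and 5.312 (2.507 to 10.22) and at day 7 2.497 and 9.117 (5.124 to 6.706). For microglia at day 3 against control, only 1 split, the real one, gave as many genes (626, highest other 2). That share, 1 of 35, is the smallest these splits allow and lies under the 0.05 set in advance. So it was, with 1 split each, for microglia at day 7 (142, highest other 14) and day 7 against day 3 (358, highest other 0). All retinal cells at day 3 gave the same share (2031, highest other 0). In retina the condition is in doubt too, because the chi-square was mixed and control microglia percentages went with the prefix. These counts therefore do not exclude chance. For microglia at day 7, pair sums gave 37 genes and thinned sums 0. For the compartments too, only the real split gave as many genes: cornea against retina (1332, highest other 1), ciliary body against retina (1281, highest other 24) and cornea against ciliary body (294, highest other 5). With the condition in doubt there, these counts do not settle chance. For all retinal cells at day 7, 2 splits gave as many genes (264, highest other 288), so chance is not excluded, and the split by library prefix gave 46. No split by prefix exists for the comparisons with ciliary body.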

How the results depend on the processing

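The alternatives without photoreceptor-rich microglia wells, without mitochondrial genes, with annotated retinal wells alone, with only macrophages and microglia and with microglia by both of the authors' calls were chosen after the data were seen. Where a value moved, the cause was not tested unless a sentence gives it.

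In microglia at day 3 against control, P2ry12, Gpr34, Sall1, Spp1, Cd63 and Top2a passed the threshold without any 1 pair. Cd207, Ccl2 and Scd2 did so for cornea against ciliary body. Over 897 named genes and comparisons, 12419 values were computed: 11113 kept direction and side of the threshold, 784 lost the call, 506 gained it and 16 turned. Leaving out a pair gave 3565 of these values, with 3000 the same, 432 weaker, 131 stronger and 2 turned. In that setting a lone pair is assumed to vary like the pairs of the other groups.

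Without control pair P2, Krt5 in microglia at day 3 turned to 2.119 and Krt12 at day 7 to 8.058, the highest of values from -6.773 and -1.723 over the pairs left out. With all annotated retinal cells in place of microglia, which adds cell types at the lesion, Lpl turned to -0.2414, C3ar1 to -0.7673, Grn to -0.03199, Ctsd to -0.5778 and Lrp1 to -0.4505 at day 3, and H2-Aa to -0.6363 and Fscn1 to 1.391 for day 7 against day 3. In annotated wells alone, all retinal cells at day 3 had Rora at 0.2099, Ighm at -0.11, Hsp90aa1 at 0.3886, Aldoa at 0.1309, Ndufa4 at 0.1411 and Lipa at -0.07776. In cells of microglia-like and macrophage-like clusters Anxa2 turned to -2.058 for ciliary body against retina.

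Genes past the threshold by the DESeq2 Wald test numbered 307 in microglia at day 3, 19 at day 7, 88 for day 7 against day 3 and 102 for cornea against ciliary body. With all annotated retinal cells the microglia counts became 1755, 775 and 218. With microglia by both of the authors' calls, which leaves fewer wells, they were 594, 19 and 179. With single libraries they were 142 for microglia at day 7, 264 for all retinal cells at day 7 and 294 for cornea against ciliary body. Thinned sums gave 0 for microglia at day 7, 1034 for cornea and 922 for ciliary body against retina, and 97 for cornea against ciliary body. Thinned sums hold fewer transcripts. Without the filter on low counts there were 468 for all retinal cells at day 7 and 425 for cornea against ciliary body, with more genes tested. Annotated wells alone gave 775 for all retinal cells at day 7, and wells of microglia-like and macrophage-like clusters 932 for ciliary body against retina.

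Leaving out each pair in turn gave 434 to 861 genes for microglia at day 3, 43 to 89 at day 7 and 142 to 315 for day 7 against day 3. All retinal cells gave 992 to 2537 at day 3 and 42 to 293 at day 7. Cornea against retina gave 869 to 1477, ciliary body against retina 735 to 1310 and cornea against ciliary body 72 to 313. The pairs behind the larger moves were control P2 and day 3 P2 (microglia at day 3: 463 and 434), control P1 and P2 (microglia at day 7: 89 and 76), day 3 P1 and P2 (day 7 against day 3: 180 and 142), day 3 P1 and P2 (all retinal cells at day 3: 1199 and 992), control P2 and day 7 P1 (all retinal cells at day 7: 293 and 42) and retina P2 (869 in cornea, 735 in ciliary body). For cornea against ciliary body they were ciliary body P4 (283), cornea P2 (313) and cornea P5 (72).

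With camera's correlation estimated, 0 gene lists passed in each of the 8 comparisons. Fry called 5 lists in microglia at day 7, 1 for day 7 against day 3, 9 and 7 in all retinal cells at day 3 and day 7, 18 for cornea against retina and 0 for cornea against ciliary body. With the preset correlation camera called 11, 3, 16, 14, 11 and 10.

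Among cell classes, the lower share of microglia at day 7 was -18.67 points at a minimum of 500 transcripts (adjusted p = 0.136) and -26.19 at 2000 (adjusted p = 0.0835), where unannotated wells of ciliary body against retina passed at -16.56. Without the mitochondrial filter the calls were lost (adjusted p from 0.0603 to 0.319): microglia -17 at day 3 and -13.48 at day 7, dendritic cells 19.45, 5.381 and, for day 7 against day 3, -14.07, and the joint class 11.37 and 8.039. So were unannotated wells of cornea at 12.57 against retina and 37.78 against ciliary body, the joint class of ciliary body at 24.88 against retina, cornea against ciliary body at -23.51, and macrophages of cornea against ciliary body at -14.27. Calls with an adjusted p of 0.0603 there had libraries that still stood fully apart, at the smallest p of the test.

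Leaving out each library gave microglia -36.14 to -27.32 points at day 3 and -27.65 to -18.82 at day 7, dendritic cells 20.48 to 25.81 and 6.366 to 8.92, and the joint class 13.29 to 16.98 and 10.22 to 13.89. Unannotated wells of cornea against retina ran from 24.14 to 32.39, the joint class of ciliary body against retina from 26.14 to 28.01 and macrophages of cornea against ciliary body from -21.75 to -12.46. With a control library left out, the smallest adjusted p of the calls against control was 0.0543. The call for microglia at day 7 was also lost without any 1 day 7 library.

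Adding the shared prefix of library names as a block gave 159 genes for microglia and 244 for all retinal cells at day 7 on single libraries, and 43 and 106 on pair sums. The pairing of prefixes across groups had little hold in the data, with correlations of pair deviations over genes from -0.0759 to 0.194. No paired analysis was possible for the compartments because they share fewer than 2 prefixes. Clustering at other resolutions was not run for shares, whose classes come from the annotation, and at most 17.3% of simulated 2-fold changes were recovered at these depths and 2 sums per group.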

Other observations

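The list tests named below were all planned.

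Among passing wells outside the annotation, 16 of 82 in ciliary body were tissue macrophage-like and 8 neutrophil-like. In cornea 14 of 333 were tissue macrophage-like and 12 neutrophil-like. In the retina, T cell-like wells outside the annotation numbered 0 of 76 in control, 4 of 107 at day 3 and 10 of 152 at day 7, and dendritic cell-like wells 0, 10 and 1. These names come from clusters and their marker lists, and no test between groups was run on them.

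Annotated microglia of the 3 retina groups were spread unequally over shared clusters of the authors' annotation. In 3 clusters lay 29, 56 and 32 control microglia, and with them 12, 9 and 15 of day 3 and 41, 16 and 13 of day 7. Of the day 3 microglia, 39 of 81 lay in another cluster, which held 1 control and 7 day 7 microglia. Of the day 7 microglia, 21 and 15 lay in 2 others that held 2 and 0 control microglia. The lists of B cell and of endothelial and mural cell markers had fewer than 3 measured genes in every comparison and were not tested. The mast cell and the lipid and cholesterol lists passed camera in none of their comparisons, with the smallest adjusted p at 0.176 and 0.125.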
